A study of Mus musculus with 10 samples.

How the data were processed

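Total RNA of C2C12 cells, a mouse myoblast line that can be induced to form myotubes, was hybridised to 1-colour (Cy3) Agilent whole-genome expression arrays after transfection with a miR-27a-3p mimic, a synthetic double-stranded RNA that supplies the mature microRNA, or with a scrambled sequence. Per the labels, the dose was 150 nM, the cells were collected 72 h after transfection, transfection efficiency was estimated at 60%, and 6 samples received the mimic and 4 the scrambled sequence. Per the labels' protocols, RNA was extracted with TRIzol and amplified and labelled with a low-input kit. No untreated cells were analysed here, so every difference is mimic minus scrambled sequence.

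The deposited scanner files hold spot intensity on a linear scale, per the file headers the background-subtracted and detrended processed signal of Agilent Feature Extraction, beside the mean and local background intensity of each spot. The file headers name Feature Extraction 12.0.0.7 and the mm9 mouse genome build for probe positions, whereas the submitters' processing notes name version 10.7.3.1, and nothing else in the sources used here settles which was run. A deposited value table of the same arrays held 1 intensity per probe. Set against the scanner signals, each of its columns was linear, not centred and ordered as the processed signal (Spearman correlation across probes of 0.9987 or more), with values that had been quantile-normalised, as seen from the values themselves. Its columns had medians of 192.1, 275.6, 260, 214.7, 252.7 and 294.2 for mimic replicates 1 to 6 and of 245, 244.8, 202.9 and 214.9 for scrambled replicates 1 to 4. It left most dim probes empty by a rule that stays unknown, and it served as an alternative only.

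All 10 files came from 1 slide. They fell into 5 array positions, each scanned 2 times, with 1 file per scan: mimic replicates 1 and 4, 2 and 5, and 3 and 6 shared a position, as did scrambled replicates 1 and 3, and 2 and 4. The 2 files of a position shared 24 to 81 spots marked as non-uniform, against 0 or 1 for any other pair of files, and their deviations from the mean of the group within a scan correlated at 0.81 to 0.95 across probes. Pairs from different groups reached 0.64 on this measure, and with 2 scrambled arrays per scan their deviations mirror each other by construction. Residuals of repeated spots correlated at 0.19 to 0.82 within a position and at up to 0.26 in other pairs, so the pairing rests on the positions and the shared spots. The labels state that transfections were repeated independently for every replicate, and the files do not show how 1 position could carry 2 samples. The 2 files of a position were therefore averaged and counted as 1 replicate, which left n = 3 mimic arrays and n = 2 scrambled arrays, named here mimic arrays 1, 2 and 3 and scrambled arrays 1 and 2 in the order of the replicate pairs above. The design fixed before the data were examined took all 10 files as separate arrays, and this is reported as an alternative. The p-values measure the spread between these 5 arrays, which may be partly technical.

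The processed signal was taken as log2, control spots and spots marked as outliers (157 to 270 per file) were left out, and spots of 1 probe were averaged. From each file its 75th percentile over the 13029 probes well above background in all 10 files was subtracted, because under 50% of the probes were detected. Probes well above background in at least 4 of the 10 files, in whichever group, were kept (16786 of 55681). Each gene was represented by its probe with the highest mean signal, which gave 13188 genes and transcripts; 50 were left out for want of an unmarked value on an array, and 13138 were tested. Probes were named through their transcript accession in the RefSeq gene table of GRCm38.p6 (28026 probes), through the current symbol (3418) or an older one (295), and otherwise kept the name in the file (23942); the name differed from that in the file for 1946. That table served for names only, and positions are those of the probes on mm9 in the files. No called gene had another probe called in the opposite direction. Between 27.0% and 35.3% of the spots of a file, controls left out, were well above background, with a median signal of 428 to 783 among them. No spot other than controls, which were not counted, was saturated. The slope of log2 signal over log2 concentration of the spike-in controls was 0.968 to 1.04. The number of arrays limits the precision.

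Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 3 residual and 2.93 prior degrees of freedom), with Benjamini-Hochberg adjustment over the 13138 genes and transcripts and a threshold of 0.05, and all adjusted p-values of genes come from this model. A gene past the threshold is said to have risen or fallen. A gene well above background in no file of a group has only a bound there, given as "at least N-fold": the mean of the brighter group against, on each array of the dimmer group, the higher of the lowest signal among probes well above background and the probe's own signal. Gene lists were tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation, with fry, and with an exact two-sided permutation test of the mean list value per array over the 10 splits of 5 arrays into 3 and 2, whose smallest possible p is 0.1; p-values of lists were adjusted over the 32 lists tested. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

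Of 33 lists fixed before the data were examined, 32 had measured members: published miR-27 targets; glycolysis; glycogen metabolism; fatty acid oxidation; adipogenesis and lipid storage; cholesterol biosynthesis; the TCA cycle; oxidative phosphorylation; mitochondrial biogenesis and dynamics; myogenic regulators and myoblast markers; muscle differentiation and contractile genes; cell cycle; p53 targets and cell cycle inhibitors; apoptosis; interferon and double-stranded RNA response; NF-kB and inflammatory response; extracellular matrix; TGF-beta, myostatin and BMP signalling; Wnt signalling; insulin, IGF and FoxO signalling; MAPK and growth factor signalling; atrophy, ubiquitin ligases and autophagy; proteasome; unfolded protein and integrated stress response; oxidative stress response; heat shock and chaperones; microRNA pathway; ribosomal proteins; housekeeping controls; and markers of osteoblasts, of fibroblasts and smooth muscle, and of endothelial and blood cells. None of the 11 adipocyte markers was measured, so that list has no result. The rule for named genes, fixed at the same time, took the 12 largest falls and the 12 largest rises among called genes with a plain symbol whose mimic and scrambled files did not overlap, and from each list up to 4 called members with the smallest p, or 2 members where none was called. Tests of miR-27a-3p seed sites in 3' UTRs, which were also fixed then, were not run, since no 3' UTR sequences were used here.

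The alternatives were normexp background correction with an offset of 50, quantile normalisation, the median or the percentile over all probes as the scale, the value table, no filter on dim probes or only probes well above background in all files, the mean of a gene's probes or every probe, eBayes with trend and robust, array weights, the replicate number or the scan as a block, each scan alone, a 1.5-fold threshold, the removal of each array's trend with probe GC content (a spline with 4 degrees of freedom), and leaving out each file or each array. The fit was tested on simulated data for 13138 genes of which 200 were changed: over 20 simulations it recovered 0.224% of genes changed 1.5-fold, 18.9% at 2-fold and 70.1% at 4-fold, with a median of 2 false calls. The data gave 676 calls, which sets a less strict cutoff on the unadjusted p, so these shares do not carry over to the data. Where no gene was changed but the 2 files of a position shared their deviations, the median count called was 0 with the files averaged and 437 with 10 files taken as separate arrays. Camera called a shifted list in 20 of 20 simulations and an unshifted one in 2, at an unadjusted p under 0.05. The simulated genes varied independently of each other, so this does not test camera on lists whose genes are correlated. The estimated correlation was 0.13 for the muscle list and 0.44 for the ribosomal list. It was 0.046 for cholesterol biosynthesis and 0.021 for the fibroblast markers. For the cell cycle and extracellular matrix lists it was -0.013 and 0.0021, under the preset 0.01. A correlation above the preset is therefore not why the calls of the cell cycle and matrix lists were lost with an estimated correlation.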

Results

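Gene expression was measured in C2C12 myoblasts, a line derived from mouse skeletal muscle that proliferates in rich medium and can differentiate into contractile myotubes. The cells were transfected with a miR-27a-3p mimic (6 samples) or a scrambled sequence (4 samples) at 150 nM and collected after 72 h. miR-27a-3p is a microRNA with published targets in muscle growth, adipocyte formation and lipid metabolism. The series asks which transcripts change when this microRNA is raised in myoblasts. The 10 files held 2 scans each of 5 array positions, which were averaged to 3 mimic arrays and 2 scrambled arrays. Each file reported 62976 spots, and of the 59305 that were not controls 27% to 35.3% were well above background. Levels are log2 signals relative to the 75th percentile of detected probes, and differences are mimic minus scrambled sequence.

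After the mimic, the list of muscle differentiation and contractile genes was lower and the list of cell cycle genes higher than after the scrambled sequence. Both were called by camera and neither with an estimated correlation (adjusted p = 0.376 and 0.124). Of 13138 genes and transcripts tested with limma, 676 differed at the adjusted p threshold of 0.05, 308 lower and 368 higher. By fitted fold, 216 of them were lower and 241 higher by 2-fold or more. Fitted folds rest partly on signals not above background, so some of these genes, such as Cyb561, have a bound under 2-fold. Among the 9691 with a plain gene symbol, 264 fell and 320 rose. The first principal component held 59.6% of the variance and placed the mimic arrays at -23.9, -25.8 and -23.6 and the scrambled arrays at 18.1 and 55.2. The scrambled arrays differed from each other more than any pair of mimic arrays did, with an SD of log2 differences of 0.56 against 0.32 to 0.44. Scrambled array 1 lay closer to mimic arrays 1 and 2 (SD 0.50 and 0.54) than to scrambled array 2.

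The count of called genes depended on single arrays. It was 47, 79 and 138 without mimic array 1, 2 or 3, 4352 without scrambled array 1 and 571 without scrambled array 2. Taken as 10 separate arrays, the fit fixed beforehand, the files gave 4512 calls, of which 673 were shared in direction with the 676. With the scan as a block and the array position as a random block, 1459 genes were called, and within the first and the second scan alone 584 and 533. The lower calls made up 45.6% of all calls, and 31.8% of the 737 calls when the percentile was taken over all probes, a scaling that moved the median difference of all genes from -0.05 to 0.11.

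The largest fitted falls included 2 apolipoprotein genes and 4 muscle genes. Apoc1 and Apoe, neighbouring apolipoprotein genes on chromosome 7 (mm9 probe positions 20274831 to 20274890 and 20281732 to 20281791), were well above background in all 4 scrambled files and in no mimic file, at least 5.37-fold and at least 6.25-fold lower (adjusted p = 0.0086 and 0.0040). Srpk3, a muscle-specific protein kinase, and Ankrd2, a stretch-responsive muscle protein, were at least 6.11-fold and at least 5.31-fold lower (adjusted p = 0.0048 and 0.011), also with no mimic file above background. Csrp3, a muscle LIM protein, fell by 3.04 ± 0.39 (SE, log2, adjusted p = 0.016), with signal above background in 1 of 6 mimic files, and Chrng, the embryonic subunit of the acetylcholine receptor, fell by 2.80 ± 0.34 (adjusted p = 0.013), above background in 4 of 6. Cyp2f2, a cytochrome P450, fell by 4.07 ± 0.26 (adjusted p = 0.0036, 3 of 6 mimic files above background). Slc2a6, a sugar transporter, fell by 2.97 ± 0.26 (adjusted p = 0.0072, 5 of 6). No mimic file was above background for the 4 other genes. Ramp3, a receptor activity-modifying protein, was at least 4.72-fold lower and Sparcl1, a matricellular protein, at least 3.75-fold (adjusted p = 0.0045 and 0.0086). Nup210, a nuclear pore protein, was at least 2.88-fold lower and Tm6sf1 at least 2.78-fold (adjusted p = 0.012 and 0.0031). The order by fitted fold is not established for genes given as a bound or above background in only part of the mimic files, and the fitted falls of the latter rest partly on signals not above background.

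The largest fitted rises included an integrin gene and 2 genes of the prolactin family. Itgb4, the integrin subunit of hemidesmosomes (chromosome 11, 115869666 to 115869725), was well above background in all 6 mimic files and in no scrambled file and was at least 8.09-fold higher (adjusted p = 0.0031). The same files were above background for Slurp1, a secreted protein of keratinocytes (at least 6.21-fold higher, adjusted p = 0.0040), and Scara5, a scavenger receptor that binds ferritin (at least 6.04-fold, adjusted p = 0.0017). This was also so for Cd200r4 and Tmem184a (at least 5.04-fold and at least 3.15-fold, adjusted p = 0.0020 and 0.0055). The non-coding transcript Platr26 and Cyb561, a cytochrome b561, were at least 2.15-fold and at least 1.91-fold higher on the same pattern of files (adjusted p = 0.0031 and 0.0036). Their place among the largest rises rests on scrambled signals not above background. Prl2c5 and Prl2c1, members of the proliferin group of prolactin-like genes on chromosome 13, were measured in all files and rose by 3.51 ± 0.14 and 2.96 ± 0.14 (SE, log2, adjusted p = 0.0017 and 0.0020). For Prl2c5 the level went from -2.09 ± 0.05 (SD, n = 2) to 1.42 ± 0.08 (SD, n = 3). The genes of this family are near-identical, and a probe can take up transcripts of several. Anxa8, an annexin, rose by 2.93 ± 0.18 (adjusted p = 0.0031). Tmem45a rose by 3.08 ± 0.13 (adjusted p = 0.0019, 3 of 4 scrambled files above background) and Mgll, which releases fatty acids from monoglycerides, rose by 3.03 ± 0.43 (adjusted p = 0.019, 1 of 4), so that the size and rank of these 2 rises rest partly on signals not above background.

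**Figure D1:**
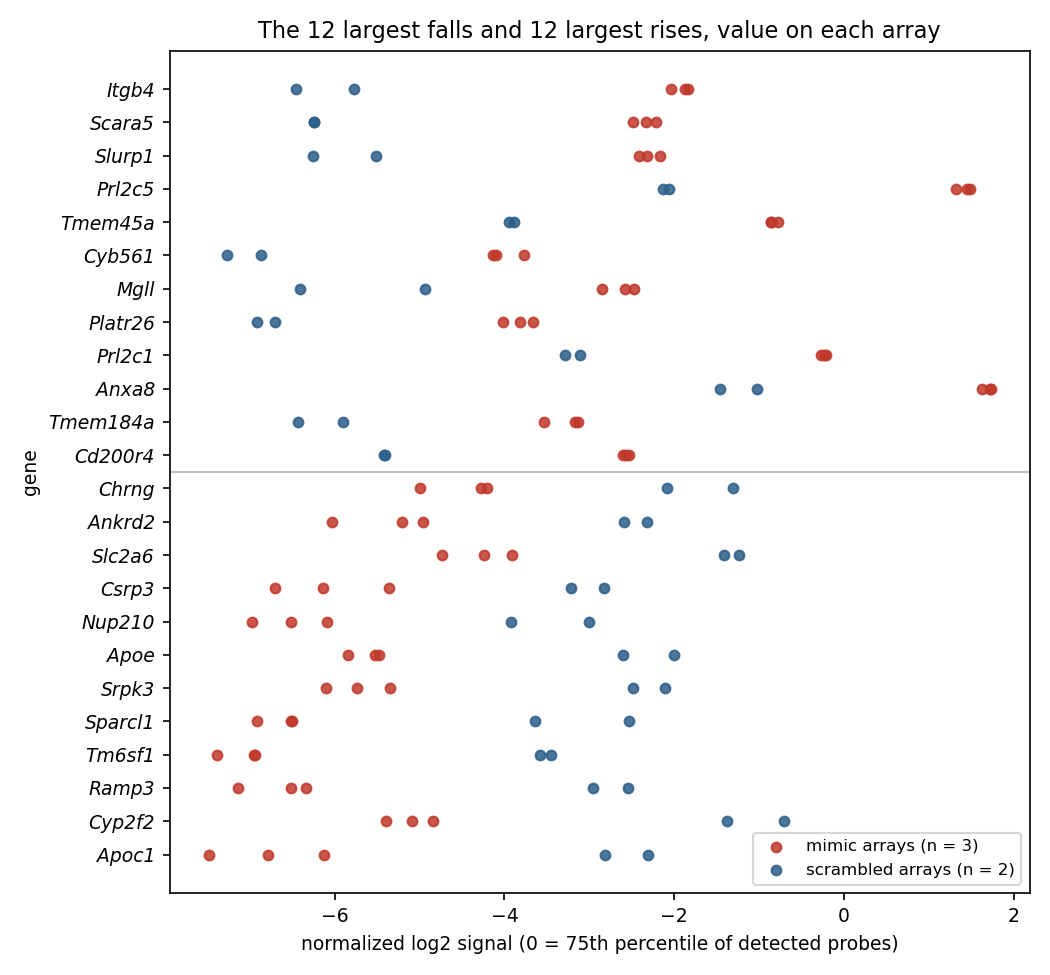
Normalised log2 signal of the 12 genes with the largest fitted rises (upper part) and the 12 with the largest fitted falls (lower part) on each of the 3 mimic arrays (red) and 2 scrambled arrays (blue), each point the mean of 2 scans, with 0 at the 75th percentile of detected probes. The rule that picked these genes required that the groups do not overlap. Most values of the dimmer group lie below -4, where signal was not well above background in part or all of the files.

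Muscle differentiation and contractile genes were lower as a list, with the smallest camera p of the 32 lists. Of 41 tested members, 22 fell, 1 rose and 18 did not pass the test, and adjusted over the list alone 31 fell and 1 rose. Myog, the transcription factor that starts terminal myoblast differentiation (chromosome 1, 136188874 to 136188933), fell by 2.10 ± 0.21, from 2.52 ± 0.43 (SD, n = 2) to 0.42 ± 0.09 (SD, n = 3, adjusted p = 0.0092). Mymx, a membrane peptide needed for myoblast fusion, fell by 1.56 ± 0.16 (adjusted p = 0.0095), and the troponins Tnnc2 and Tnnt1 fell by 1.55 ± 0.15 and 1.36 ± 0.13 (adjusted p = 0.0084 and 0.0090). The exception, Myf6, a myogenic factor named after its value was seen, rose by 0.70 ± 0.14 (adjusted p = 0.049). The median difference of the list was -1.52, or -1.48 with 1 member at its bound, and camera gave an adjusted p = 1.8e-13. The call was lost with an estimated correlation (adjusted p = 0.376). List means were -1.29, -1.24 and -1.78 on the mimic arrays and -0.20 and -0.05 on the scrambled arrays (exact permutation p = 0.1, the smallest that 10 splits allow). The median was -1.52 with the scan as a block and -1.45 and -1.54 within the scans, and it stayed past the threshold without any 1 array.

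Regulators of the myogenic lineage moved both ways. Of 20 tested members of the list of myogenic regulators and myoblast markers, 3 fell, 1 rose and 16 did not pass the test, and adjusted over the list alone 10 fell and 4 rose. Heyl, a transcriptional target of Notch, fell by 2.70 ± 0.25 (adjusted p = 0.0084, 3 of 6 mimic files above background), and the Notch ligand Dll1 fell by 1.39 ± 0.13 (adjusted p = 0.0083, 3 of 6). Cd34, a surface marker of quiescent satellite cells, rose by 1.56 ± 0.18 (adjusted p = 0.012). The list as a whole did not pass camera (median -0.45, adjusted p = 0.331) and passed fry, lower (adjusted p = 0.0059). Myod1, named after its value was seen, was at -1.26 ± 0.31 and missed the threshold (adjusted p = 0.080).

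Cell cycle genes shifted in the opposite direction. Of 44 tested members, 14 rose, 0 fell under limma and 30 did not pass, against 22 higher and 1 lower adjusted over the list alone and 24 higher and 2 lower at an unadjusted p under 0.05. Kif20a and Prc1, which act in cytokinesis, rose by 1.05 ± 0.15 and 1.21 ± 0.20 (adjusted p = 0.019 and 0.031). Ccnd1, the cyclin of the G1 phase, rose by 1.14 ± 0.18 and Ccna2, the cyclin of S phase and G2, by 0.94 ± 0.15 (adjusted p = 0.028 for both). The median difference was 0.64 with an adjusted p = 1.7e-10 from camera, which became an adjusted p = 0.124 with an estimated correlation. Mean levels were -0.84, -0.82 and -0.86 on the mimic arrays and -1.35 and -1.38 on the scrambled arrays (exact permutation p = 0.1). The median was 0.64 with the scan as a block, which again cannot move it, and 0.66 and 0.57 within the scans. The call held without any 1 array.

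**Figure D2:**
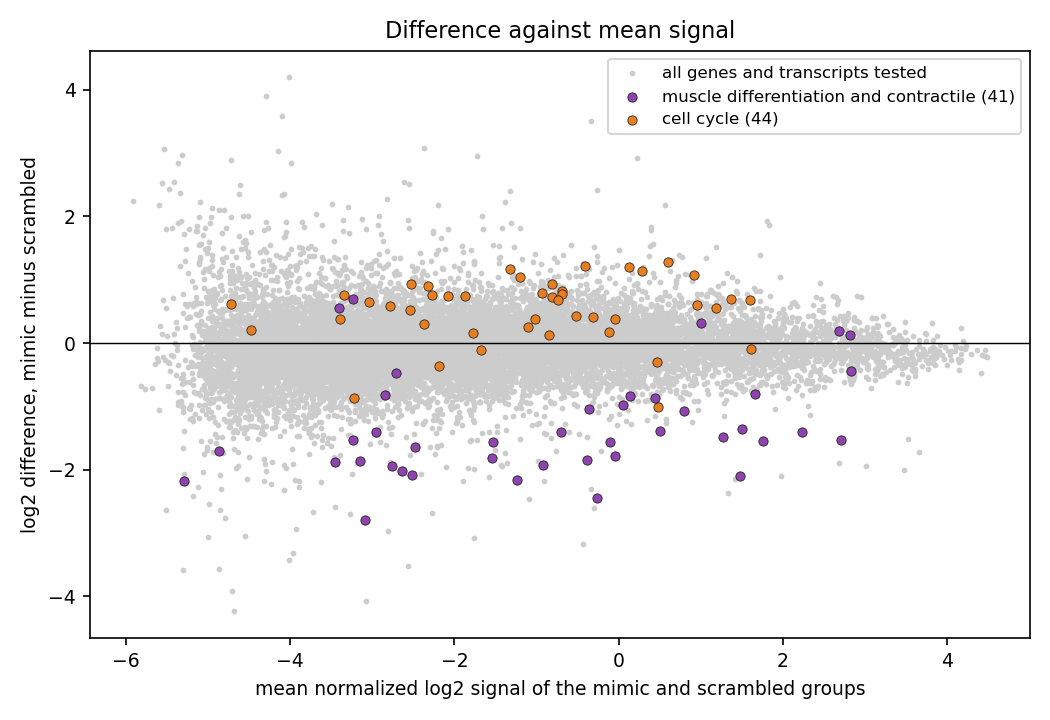
Log2 difference, mimic minus scrambled sequence, against the mean normalised log2 signal of both groups for all 13138 genes and transcripts tested (grey), with the 41 muscle differentiation and contractile genes in purple and the 44 cell cycle genes in orange. Of the purple points 36 lie below 0, and of the orange points 38 lie above it.

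Extracellular matrix genes were higher on balance. Of 39 tested members, 4 rose and 1 fell, and adjusted over the list alone 10 rose and 3 fell. Nid1, a basement membrane glycoprotein, rose by 1.40 ± 0.15 (adjusted p = 0.010), Timp3, an inhibitor of matrix proteases, by 0.97 ± 0.14 (adjusted p = 0.019) and the collagen Col12a1 by 1.11 ± 0.20 (adjusted p = 0.038, 3 of 4 scrambled files above background). Col8a1 was at least 1.48-fold higher (adjusted p = 0.016), above background in 4 of 6 mimic files and no scrambled file. Loxl1, an enzyme that crosslinks elastin, named after its value was seen, fell by 0.88 ± 0.17 (adjusted p = 0.047). The median was 0.24 with an adjusted p = 0.0046, and an adjusted p = 0.376 with an estimated correlation. It was 0.24 with the scan as a block, which cannot move it, and 0.23 and 0.27 within the scans. Without scrambled array 1 the median was 0.13 and the call was lost (adjusted p = 0.167).

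The 3 other lists past camera's threshold had smaller margins and lower levels after the mimic, and none passed with an estimated correlation. The 5 measured markers of fibroblasts and smooth muscle had a median of -0.71 (adjusted p = 0.028, and 0.442 with an estimated correlation), with 2 lower, and 3 lower adjusted over the list alone. Tagln, an actin-binding protein of smooth muscle, fell by 1.01 ± 0.15 (adjusted p = 0.021), and Pdgfra, a growth factor receptor of fibroblasts, fell by 0.96 ± 0.16 (adjusted p = 0.030). Pdgfra was above background in 1 of 6 mimic and 3 of 4 scrambled files and was at 1.28, the opposite sign, in the deposited value table (adjusted p = 0.657), where the list had a median of -0.07 and was not called (adjusted p = 0.272). The 24 measured cholesterol biosynthesis genes had a median of -0.44 (adjusted p = 0.046, and 0.442 with an estimated correlation), and 1 of them was called. Fdft1, which makes squalene, fell by 1.16 ± 0.15 (adjusted p = 0.017). Adjusted over the list alone, 4 cholesterol genes were lower and 1 higher, and the scrambled arrays themselves lay 0.38 apart in the list's mean. None of 49 ribosomal protein genes was called by limma, also when adjusted over the list alone, and 2 had an unadjusted p under 0.05. Of the 49, 47 were negative, with a median of -0.18 (adjusted p = 0.026, and 0.699 with an estimated correlation). Rps9 was at -0.41 and Rpl3 at -0.39 (adjusted p = 0.160 and 0.178), and Rpl3 at -0.25 without scrambled array 2. The fibroblast call was lost without mimic array 1, scrambled array 1 or scrambled array 2 (adjusted p = 0.057, 0.076 and 0.067), and the cholesterol call without the same arrays (0.057, 0.097 and 0.067). The ribosomal call was lost without mimic array 1, mimic array 2 or scrambled array 2 (0.153, 0.060 and 0.325) and with probe GC content corrected (0.273). The ribosomal median was -0.08 without scrambled array 2 and -0.29 without scrambled array 1. Leaving out 1 file ended the cholesterol call for 6 of the 10 files (adjusted p = 0.053 to 0.070) and the ribosomal call for 5 (0.052 to 0.168). It was also lost under 3 other scalings: the ribosomal median was -0.04 with quantile normalisation, -0.05 in the deposited value table and -0.03 with the percentile over all probes (adjusted p = 0.400, 0.358 and 0.195). With only probes well above background in all files, the cholesterol median was -0.07 and the call was lost (adjusted p = 0.262), as it was with normexp (median -0.28, adjusted p = 0.061). The fibroblast call was lost in 4 more settings: normexp, quantile normalisation, only probes above background in all files and no filter on dim probes (adjusted p = 0.055, 0.058, 0.114 and 0.306). It was lost with every probe tested as well (adjusted p = 0.093). With the scan as a block the cholesterol call was lost (adjusted p = 0.065) and the other 2 held (0.025 and 0.0058). Within each scan all 3 held. Fry called the fibroblast and cholesterol lists lower (adjusted p = 0.013 and 0.043) and did not call the ribosomal list (0.215). Not every loss of the ribosomal call is given here, and it held in 19 of 35 alternatives. That count includes the 1.5-fold threshold and eBayes with trend and robust, which could not change camera's result.

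**Figure D3:**
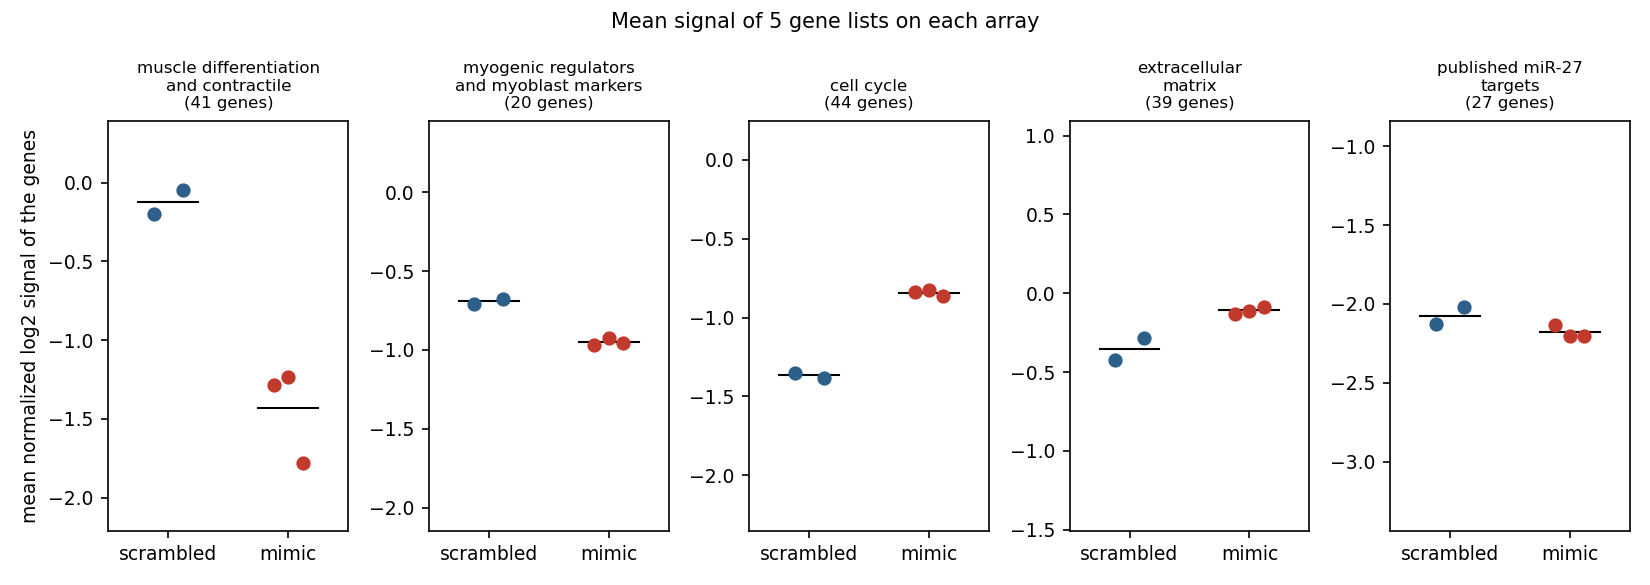
Mean normalised log2 signal of the tested members of 5 gene lists on each scrambled array (blue, n = 2) and mimic array (red, n = 3), with group means as lines; all panels span the same number of log2 units. The mean of the 41 muscle differentiation and contractile genes was -0.12 on the scrambled and -1.43 on the mimic arrays, and that of the 27 published miR-27 targets -2.08 and -2.18.

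Published targets of miR-27 did not pass the test as a list. Of 37 genes, 27 were measured and 0 passed limma's threshold, over all genes or adjusted over the list alone. An unadjusted p under 0.05 was found for 5 lower and 1 higher members, and fry gave the list an adjusted p = 0.190. The median difference was -0.11 (adjusted p = 0.777), 16 were negative and 11 positive, and the median was 0.05 with the percentile over all probes. The members with the smallest p were Smad2, a mediator of TGF-beta and myostatin signals, at -0.76 ± 0.17 (adjusted p = 0.067) and Pparg, the regulator of adipocyte formation, at -0.54 ± 0.14 (adjusted p = 0.088). In the microRNA pathway 1 of 20 genes was called, Tnrc6b, a partner of Argonaute proteins, which fell by 0.78 ± 0.15 (adjusted p = 0.045, 3 of 6 mimic files above background). The list had a median of -0.09 (adjusted p = 0.710), with 1 call adjusted over the list alone.

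Lists of energy metabolism held few called genes and none passed camera in the main analysis. Fry, which does not compare a list with other genes, called fatty acid oxidation, the TCA cycle and mitochondrial biogenesis lower (adjusted p = 0.032, 0.0025 and 0.013). With probe GC content corrected, a setting chosen after seeing the data, camera called these 3 lists lower too (adjusted p = 0.039, 0.039 and 0.048). Fatty acid oxidation came closest (24 genes, median -0.23, adjusted p = 0.063), with 2 lower members. The mitochondrial uncoupling proteins Ucp2 and Ucp3 were at least 2.82-fold and at least 2.00-fold lower (adjusted p = 0.025 for both), above background in no mimic file. In the TCA cycle (26 genes, median -0.22, adjusted p = 0.159) Suclg1 fell by 0.91 ± 0.14 and Pcx, pyruvate carboxylase, by 0.82 ± 0.16 (adjusted p = 0.028 and 0.048). In oxidative phosphorylation (54 genes, median -0.10, adjusted p = 0.294) Cox6a2, the muscle isoform of a cytochrome oxidase subunit, fell by 1.20 ± 0.19 (adjusted p = 0.029). In glycogen metabolism (17 genes, median -0.16, adjusted p = 0.551) the glycogen synthase Gys1 fell by 1.13 ± 0.22 (adjusted p = 0.046). Glycolysis (22 genes, median 0.03, adjusted p = 0.461) held 0 calls by limma and 4 members with an unadjusted p under 0.05, with Slc16a3 at 0.76 and Pfkfb3 at 1.19 (adjusted p = 0.089 and 0.163, Pfkfb3 above background in 3 of 4 scrambled files). Pfkfb3 was at 0.46 without scrambled array 2 and at 1.92 without scrambled array 1. Mitochondrial biogenesis and dynamics (24 genes, median -0.26, adjusted p = 0.204) held 0 calls and 6 such members, with Tfam at -0.67 and Phb2 at -0.60 (adjusted p = 0.060 and 0.132), and Phb2 at -0.33 without scrambled array 2. In adipogenesis and lipid storage (16 genes) Mgll was the only call, and median and mean differed in sign (-0.29 and 0.05, test direction down, adjusted p = 0.727). Adjusted over the list alone, there were 3 lower calls each in fatty acid oxidation and the TCA cycle and 1 in oxidative phosphorylation. Glycogen metabolism and adipogenesis each had 3 lower and 1 higher, and glycolysis and mitochondrial biogenesis had 0.

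Signalling lists held members that moved in both directions, and none passed camera in the main analysis. Fry called the inflammatory and MAPK lists lower (adjusted p = 0.043 and 0.0097), and camera the MAPK list with probe GC content corrected (adjusted p = 0.034). Of 13 measured genes of the NF-kB and inflammatory response, the chemokines Ccl2, Cxcl5 and Cxcl1 fell by 1.29 ± 0.14, 1.26 ± 0.14 and 1.22 ± 0.18 (adjusted p = 0.011, 0.010 and 0.024, Cxcl1 above background in 5 of 6 mimic files), as did Ccl7 by 0.82 ± 0.15, named after its value was seen (adjusted p = 0.042). Ptgs2, the inducible cyclooxygenase, rose by 1.82 ± 0.14 (adjusted p = 0.0055). The list had a median of -0.25 (adjusted p = 0.219). In TGF-beta, myostatin and BMP signalling (33 genes, median -0.01 but mean 0.12 and test direction up, adjusted p = 0.331) Bmp4 and Ltbp1 rose by 1.40 ± 0.15 and 0.98 ± 0.16 (adjusted p = 0.010 and 0.028), and Tgfbr3 fell by 0.87 ± 0.16 (adjusted p = 0.040). In MAPK and growth factor signalling (32 genes, median -0.31, adjusted p = 0.159) Pdgfrb fell by 1.14 ± 0.13 and Fgfr4 by 0.74 ± 0.14, beside Pdgfra, and Etv4 rose by 1.05 ± 0.21 (adjusted p = 0.012, 0.040 and 0.048, Fgfr4 above background in 4 of 6 mimic files). In insulin, IGF and FoxO signalling (27 genes, median -0.12, adjusted p = 0.551) Igf2, a growth factor of differentiating myoblasts, fell by 2.67 ± 0.34 (adjusted p = 0.016, 2 of 6 mimic files above background). In Wnt signalling (22 genes, median -0.08 but mean 0.04 and test direction up, adjusted p = 0.635) the secreted inhibitor Sfrp2 rose by 1.31 ± 0.13 (adjusted p = 0.0090, 3 of 4 scrambled files above background). Adjusted over the list alone, the lower and higher calls were 4 and 1 in the inflammatory list, 4 and 8 in TGF-beta, 7 and 1 in MAPK, 2 and 2 in insulin and 1 and 3 in Wnt signalling.

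No list of stress, death or protein turnover passed camera in the main analysis. Fry called heat shock and the proteasome lower and p53 targets higher (adjusted p = 0.00033, 0.043 and 0.043), and camera called heat shock lower with probe GC content corrected (adjusted p = 0.048). Of 17 measured genes of the interferon and double-stranded RNA response, which a transfected RNA can induce, Xaf1 rose by 0.90 ± 0.15 and Igtp fell by 1.17 ± 0.22 (adjusted p = 0.034 and 0.044), and the list had a median of 0.17 (adjusted p = 0.502). Among p53 targets and cell cycle inhibitors (23 genes, median 0.06, adjusted p = 0.403) 2 genes rose. Perp, a desmosomal protein, was at least 1.60-fold higher (adjusted p = 0.0070), above background in 4 of 6 mimic files and no scrambled file. The death receptor Fas rose by 1.60 ± 0.25 (adjusted p = 0.028), above background in 1 of 4 scrambled files, so that the size of this rise is uncertain. In heat shock and chaperones (21 genes, median -0.20, adjusted p = 0.093) Hsph1 and Cct3 fell by 1.13 ± 0.15 and 1.01 ± 0.14 (adjusted p = 0.018 for both). In the oxidative stress response (26 genes, median 0.12, adjusted p = 0.447) Mgst1 fell by 1.48 ± 0.16 and Nqo1 rose by 1.07 ± 0.20 (adjusted p = 0.010 and 0.040, Mgst1 above background in 5 of 6 mimic files). Vldlr, a lipoprotein receptor, rose by 1.05 ± 0.20 (adjusted p = 0.044) in the unfolded protein and integrated stress response (30 genes, median -0.05 but mean 0.02 and test direction up, adjusted p = 0.617). Map1lc3a, an autophagosome protein, fell by 1.71 ± 0.33 (adjusted p = 0.045) in atrophy, ubiquitin ligases and autophagy (28 genes, median -0.05, adjusted p = 0.848), and was at -1.14 without scrambled array 2. Limma called 0 of 22 apoptosis genes (median -0.01, adjusted p = 0.848), 7 of which had an unadjusted p under 0.05. Limma called 0 of 31 proteasome genes (median -0.10, adjusted p = 0.294), 4 of which had an unadjusted p under 0.05, among them Psmd6 at -0.47 and Psmd11 at -0.48 (adjusted p = 0.114 and 0.135). Adjusted over the list alone, the lower and higher calls were 1 and 2 in the interferon list, 3 and 3 among p53 targets, 2 and 0 in heat shock, 1 and 3 in oxidative stress, 2 and 3 in the atrophy list, and 0 in the unfolded protein, apoptosis and proteasome lists.

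Markers of other cell types and control genes gave no uniform shift beyond the fibroblast list. Of 4 measured osteoblast markers 1 was called, and 1 lower and 1 higher adjusted over the list alone. Spp1, the matrix protein osteopontin, fell by 1.05 ± 0.17 (adjusted p = 0.029), and the list had a median of 0.23 and a mean of -0.04 (test direction up, adjusted p = 0.682). The 6 measured endothelial and blood cell markers held 0 calls by limma, over all genes or adjusted over the list alone, and 1 unadjusted p under 0.05 (median 0.19, adjusted p = 0.403). The smallest p-values were those of Cd68 at 0.53 and Hba-a1 at 0.47 (adjusted p = 0.095 and 0.449, Hba-a1 above background in 3 of 4 scrambled files). Of 15 housekeeping controls Tfrc, the transferrin receptor, was at -0.83 ± 0.17 and passed narrowly (adjusted p = 0.050, 2 of 6 mimic files above background), also adjusted over the list alone. The median of the controls was -0.11 (adjusted p = 0.507) and turned positive under 3 of 4 other scalings. The sign of the median also turned under at least 1 of those scalings for the published miR-27 targets, oxidative phosphorylation, apoptosis, TGF-beta, Wnt, insulin and the atrophy, proteasome, unfolded protein and microRNA pathway lists, and for 0 of the 6 lists past the threshold.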

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

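Alternatives chosen after seeing the data were leaving out whole arrays, the percentile over all probes and the correction for probe GC content. The fit of the fixed design, 10 files as separate arrays, became an alternative once the files were seen to pair, and the planned blocks of replicate number and scan were run on the 10 files. The lists of muscle and cell cycle genes kept their direction and their call in 34 of 35 alternatives each, with medians of -1.57 to -1.24 and 0.50 to 0.79, and lost it only with an estimated correlation. Extracellular matrix genes kept theirs in 33 (without scrambled array 1 also lost), fibroblast markers in 25, cholesterol biosynthesis in 22 and ribosomal proteins in 19, none with a change of direction. These counts are not counts of independent checks. The 1.5-fold threshold and eBayes with trend and robust could not change camera's result and returned the main adjusted p for all 6 lists. Leaving out 1 file removed 1 scan of an array and kept the other, so it tested little. Of the 676 calls (308 lower, 368 higher), without a filter on dim probes 17 were left (6 and 11) and with array weights 180 (75 and 105). The count rose to 1459 (754 and 705) with the scan as a block and to 4512 (2541 and 1971) with 10 files as separate arrays, a setting that called genes in unchanged simulated data too. Leaving out whole arrays gave 47 to 4352 calls, 17 to 2464 lower and 30 to 1888 higher, and 3 to 7 lists. With fewer mimic arrays a test has fewer samples. Where 1 scrambled array was left, it was assumed to vary like the mimic arrays. Leaving out 1 file at a time gave 574 to 661 calls. The number of lists past the threshold was 0 with an estimated correlation, 14 with fry, which does not compare a list with other genes, and 10 with probe GC content corrected, against 6. The correction added fatty acid oxidation, the TCA cycle, mitochondrial biogenesis, MAPK and heat shock, all lower, and ended the ribosomal call. Elsewhere the cause was not tested.

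Of the 76 genes past the threshold that the naming rule picked, 21, 26 and 33 stayed past it without mimic array 1, 2 or 3, and 76 and 61 without scrambled array 1 or 2. Pdgfra was reversed with the deposited value table (1.28), and Hba-a1, not called, was at -0.17 without scrambled array 2 and at 1.11 without scrambled array 1; the cause was not tested. The tests of seed sites in 3' UTRs and their alternatives, the shortest 3' UTR and matching on length, were not run. Signal over background limits the falls and rises given as bounds, and genes under background in 7 or more files were not tested.

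Replicate numbers were shared between groups, and as a block on the 10 files they gave 1950 calls (1078 lower, 872 higher), 664 of them shared with the 676. The numbers did not pair samples: the deviations of same-numbered samples correlated at 0.38, -0.04, -0.35 and -0.10, and 1 of 4 numbers correlated best with its own.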

Other observations

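The tests that removed the trend with probe GC content were chosen before their results were seen, and the comparison with each scrambled array alone, the splits of the arrays, the scatter of repeat probes and the seed match test only afterwards. The gene groups below, outside the fixed lists, were put together after the values were seen, so their counts carry no test. Of 11 measured genes of the neuromuscular junction, 6 fell, among them Dok7 by 1.74 ± 0.13 (SE, log2, limma adjusted p = 0.0055), Chrnb1 by 1.64 ± 0.32 (adjusted p = 0.048) and Lrp4, the agrin receptor, by 1.16 ± 0.17 (adjusted p = 0.023), beside Chrng, Chrnd and Musk. Rapsn, which clusters the acetylcholine receptor, was at -0.05 (adjusted p = 0.879). Of 17 genes of the sarcoplasmic reticulum and calcium release, 10 fell, among them Mrln, a micropeptide that inhibits the calcium pump, by 2.18 ± 0.24 (adjusted p = 0.011), Casq2 by 2.08 ± 0.22 (adjusted p = 0.010) and Ryr1 by 1.82 ± 0.21 (adjusted p = 0.012). Casq2, Ryr1, Cacna1s and Chrng are also in the muscle list, as are Atp2a1 and Chrna1, which were not called.

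Of 14 measured genes of epithelial adhesion and keratinocytes, Itgb4, Slurp1, Anxa8, Perp and Lamb3 rose and Pkp2 fell. Lamb3, a laminin chain that pairs with hemidesmosomes, rose by 1.45 ± 0.22 (adjusted p = 0.023), and Itga6, the partner of Itgb4, was at 0.76 ± 0.16 (adjusted p = 0.052). Of 11 chemokines, 7 fell and 2 rose. Cxcl12, Cx3cl1 and Cxcl13 fell by 1.43 ± 0.24, 1.32 ± 0.14 and 1.79 ± 0.33 (adjusted p = 0.032, 0.010 and 0.040, Cxcl13 above background in 5 of 6 mimic files), whereas Ccl9 and Ccl8 rose by 1.18 ± 0.15 and 0.90 ± 0.15 (adjusted p = 0.017 and 0.030, Ccl8 above background in 3 of 4 scrambled files). The cytokine Il33 rose by 2.40 ± 0.17 (adjusted p = 0.0046), and the osteocalcin genes Bglap2 and Bglap3, near-identical copies that a probe cannot separate, by 2.54 ± 0.14 and 2.27 ± 0.14 (adjusted p = 0.0031 for both).

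Muscle genes were lower and cell cycle genes higher after the mimic. On scrambled array 2 signals rose with probe GC content, from a median deviation of -0.13 under 40% GC to 0.29 at 50% to 55%, but with each array's trend removed the muscle median was still -1.40 and the cell cycle median 0.65, which argues against this trend as the cause. A deviation of 1 scrambled array alone is argued against by muscle medians of -1.41 and -1.43 against scrambled arrays 1 and 2. Of the 10 splits of the arrays into 3 and 2, the real split called 676 genes and no other split called any (highest other 0), and 10 splits are too few for a share under 0.05. An effect of the mimic and a difference of the cultures in density or another respect both stay open, as no test here separates them.

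Probes holding a GT repeat were lower after the mimic almost without exception. Of 135 genes measured through a probe with GTGTGTGTGT, 132 were lower, with a median of -0.64 and array medians of -0.37, -0.25 and -0.13 for the mimic and 0.11 and 0.71 for the scrambled sequence. Removing the GC trend left -0.55, against a lowest median of -0.07 in 1000 draws of other probes matched on GC content and signal, which argues against GC content as the cause. The differences scattered 0.570 times as widely as in the matched draws, so a candidate explanation is RNA with the complementary repeat that binds to all these probes and differed between arrays, most of all on scrambled array 2, rather than separate changes of 135 genes. Probes with the reverse complement were lower too (55 genes, median -0.25 with the GC trend not removed), and RNA of that 1 strand does not account for this. No matched draws were made for these 55 genes, so how much of the -0.25 is the GC trend is unknown. The signal of GT repeat probes limits 4 called falls (Fdxacb1, Hpca, Hs2st1 and 1 unnamed transcript) and none of the genes named in the report. A biological difference in such RNA stays untested.

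The seed of miR-27a-3p, positions 2 to 8, pairs with ACTGTGA, and 103 genes were measured through a probe that holds it. With the GC trend removed their median was -0.13, as low as that of 3.89% of 360 heptamers of the same base composition, whose 5th percentile was -0.11. The reverse complement, which the microRNA cannot pair with, gave -0.10 over 72 genes, and the difference of -0.03 had a permutation p of 0.670 (two-sided, 100000 permutations). Of the 103 genes 3 were called lower and 1 higher (Fisher's exact test for lower, two-sided p = 0.522). Whether seed pairing lowered these transcripts cannot be told apart from sequence effects of the probes, because a probe covers 60 bases of a transcript and 3' UTRs were not searched.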
